A study of Mus musculus with 8 samples.

How the data were processed

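RNA from the colonic mucosa of 4 male mice, 2 per genotype, was hybridised to Illumina MouseRef-8 v2.0 BeadChips, with 2 arrays per mouse and 8 arrays in all. Per the labels' protocols, total RNA was isolated with Trizol, its quality was assessed on a Bio-Rad Experion and biotinylated cRNA was made with the Illumina TotalPrep kit. BeadStudio and Partek are named without versions, per the submitters' processing notes; the scanner settings and the summary of beads to rows are not given in the sources used here.

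A table of intensity values, 1 linear signal per row and array, was deposited without normalization between arrays or background subtraction, as its values show: the lowest signal on an array lies between 44.3 and 56.1 and the mean signal between 698 and 1080. The deposited table also gives a detection value as a fraction for each row and array. Per the file headers it is a p, but it rises with the signal (rank correlation 0.945 to 0.954 by array), so it was read as 1 minus the detection p. For 13920 of the 18097 rows (76.9%) these values were whole multiples of 1/798 on every array; the other 4177 rows (23.1%) look like means over several probes, which no source used here states. The series matrix holds log2 values that the authors quantile normalized between arrays; its columns have medians of 6.84 or 6.85, keep the ranks of the raw signals (rank correlation 1) and differ from log2 signals quantile normalized here by at most 0.0057. The values are not centred.

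Background was corrected by the normexp method of limma's neqc, with the background mean and SD inferred from the detection p, an offset of 16, quantile normalization between arrays and log2. This inference used only the rows with whole-step detection values, a choice made after the file was examined, because over all rows it gave a background SD of 389 to 682 on arrays whose median signal is 102 to 129; over whole-step rows the SD was 13.7 to 24.2. The result over all rows is given in the closing section. A row was tested when its detection p was under 0.01 on at least 4 of the 8 arrays, which left 6982 rows. On an array, 6646 to 7053 rows were detected. The number of arrays and mice limits the precision, and 10199 rows were detected on no array.

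The mouse is the replicate. The 2 arrays of a mouse were averaged, and limma 3.58.1 (lmFit and eBayes, R 4.3.3, with statmod 1.5.0 for fits with the mouse as a random effect) compared 2 mice with 2 mice per row, two-sided, with Benjamini-Hochberg adjustment over the rows tested and a threshold of 0.05. Fold changes are transgenic minus control on the log2 scale, with the standard error of the moderated fit. They are on a scale with an added offset and understate changes of dim rows. Where a row was detected on no array of a genotype, the change is given as "at least N-fold", the brighter genotype's mean against, for each array of the other, the higher of the row's own value and the lowest value of a detected row on that array; no fold is given where this bound is under 1. Genes named with a change and detected on some arrays of a genotype were Sass6 and Ero1b (1 of 4 control arrays), Igf2 and Smtn (2), Hspa5 and Prf1 (3), Cyp4b1 and Egf (1 of 4 transgenic arrays) and Abhd1, Cd3d, Cd59a and Scnn1b (2).

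Rows were named through the platform annotation supplied with the series matrix: 16610 rows had 1 gene symbol, 0 had several and 1487 had none. Of these, 16598 were found by gene ID in a RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used for names and for which genes neighbour each other. The tested rows stood for 6412 genes, each represented by its row with the highest mean over the 8 arrays; no named gene had another tested row.

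The samples, designs, 36 gene lists and most alternatives were fixed before the data were examined. Gene lists were tested with camera in limma on mouse means with a preset inter-gene correlation of 0.01, for the 34 lists with at least 5 genes tested, with adjustment over these lists; camera with an estimated correlation and fry were alternatives. The adjusted p "over the list alone" adjusts a gene's p over the members of its list. Genes are named by a rule: Dnmt1; the 12 genes with the largest change in each direction among those called with both mice of a genotype beyond both of the other, filled up to 12 by the smallest p with the same condition; and from each list up to 4 called members, or the 2 with the smallest p where none was called. Genes named outside this rule are marked as chosen after their values were seen.

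The fit was tested on simulated data for 2 transgenic and 2 control mice with the real row means. There were 20 runs on 6982 rows with 200 changed rows each. The SD within genotypes was pooled over both genotypes and shuffled across rows, and rows were drawn without correlation. The larger spread between transgenic mice and any tie of spread to level were thus not simulated. Under that setting the fit recovered 16.4% of changes of size 1 on the log2 scale, 64.4% of size 2 and 88.0% of size 4, and 3.57% of its calls were false. Camera called a list of 20 genes shifted by 1 in 20 of 20 runs and 0 of 400 unshifted lists, on 6412 genes drawn without correlation between genes. Alternatives covered the unit of replication, background correction, normalization, source of values, detection filter, variance prior, threshold, each mouse left out and each array alone.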

Results

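The series profiled the colonic mucosa, the lining of the large bowel, with and without inhibition of Dnmt1, the methyltransferase that copies DNA methylation to the new strand at replication. All 4 mice carried the Dnmt1LO/LO genotype, and 2 of them also carried TgVillacIGY. The former 2 are called control mice and the latter transgenic mice here; the labels do not spell out either name. All were male, 157 days old and of a mixed 129Sv/B6/D2 background. Each mouse was measured on 2 arrays, which count as 1 replicate, so n = 2 per genotype. The mean raw signal of an array was 866 to 1080 in control mice, 698 and 753 in transgenic mouse 1, and 998 and 1019 in transgenic mouse 2.

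The first question was whether the Dnmt1 transcript itself differed. The mean raw signal of its probe (ILMN_2720451) was 790 and 665 in the 2 control mice and 214 and 203 in the 2 transgenic mice. After normalization its level was 9.29 ± 0.16 in control mice and 7.09 ± 0.49 in transgenic mice (log2, SD, n = 2), a change of -2.20 ± 0.28 (SE), or 4.60-fold lower, with both transgenic mice below both control mice. The size depends on the processing: the change was -0.64 with background from all rows and -1.73 with series matrix values. Of the 4 control arrays, 1 stood apart at 9.63, the others at 9.14 to 9.22. Over all rows tested this did not pass the threshold (limma, adjusted p = 0.129), whereas adjusted over the list alone of 11 DNA methylation genes it did (adjusted p = 0.0075). The change was -2.55 without transgenic mouse 1 and -1.86 without transgenic mouse 2, fits whose spread comes from the control mice alone. It was -2.09 without control mouse 1 and -2.32 without control mouse 2, with the spread of the transgenic mice alone. Over the alternatives with all 4 mice the limma adjusted p ran from 0.000615 to 0.618. Values under the threshold came only from fits of the 8 arrays, which take degrees of freedom from arrays. With the mouse as the replicate the smallest limma adjusted p was 0.0564, with array 1 alone. The other 10 genes of the DNA methylation list, among them the co-repressor Trim28 (0.57 ± 0.24, SE, adjusted p = 0.622), did not pass. The list as a whole did not shift (median change 0.04, mean -0.07, camera adjusted p = 0.704). In transgenic mice 1 and 2 its medians were 0.17 and 0.08, and Trim28 was at 0.82 and 0.31.

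**Figure D1:**
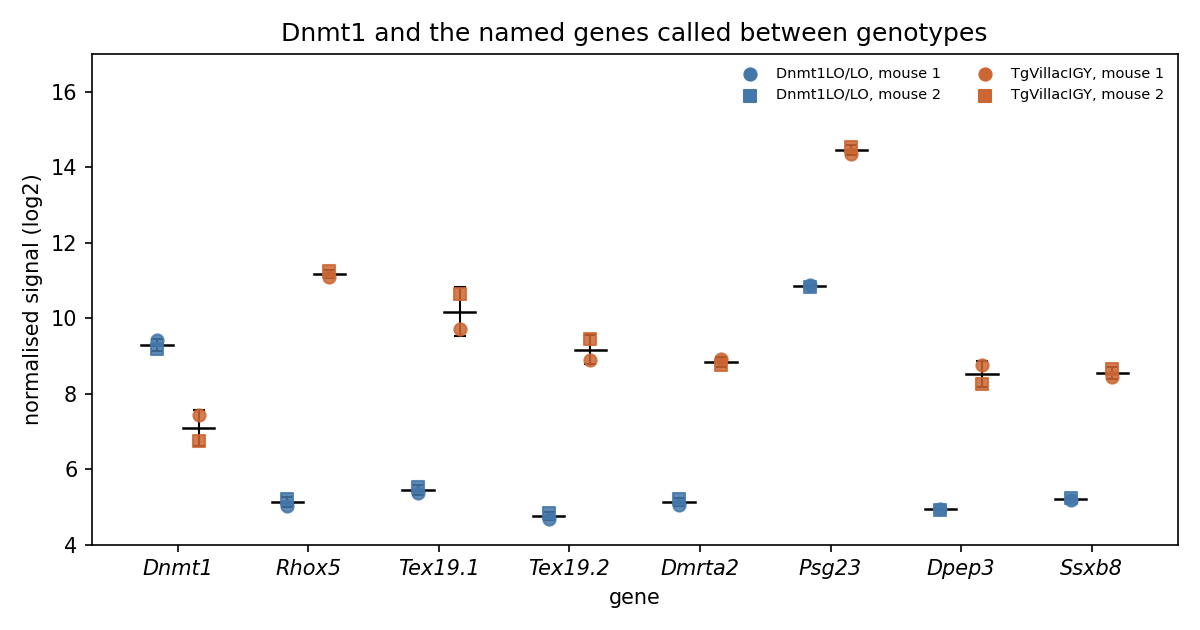
Normalised signal (log2, vertical axis) of Dnmt1 and of the 7 named genes called between genotypes (horizontal axis). Each point is a mouse, the mean of its 2 arrays, and bars give the mean and SD of 2 mice. Dnmt1 averaged 9.29 in control and 7.09 in transgenic mice and did not pass the threshold, and each of the other genes lay higher in both transgenic mice than in both control mice.

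Few rows passed the threshold between genotypes. Of 6982 rows, 9 were called and all 9 were higher in transgenic mice, 7 of them with a gene name. Rhox5 (ILMN_2762935), a homeobox gene of the reproductive tissues on the X chromosome, was at 5.12 ± 0.13 in control mice, below detection on all 4 of their arrays, and at 11.17 ± 0.11 in transgenic mice (log2, SD, n = 2), at least 26.6-fold higher (limma, adjusted p = 0.0034). The germ cell genes Tex19.1 (ILMN_2615917) and Tex19.2 (ILMN_1212878), which are neighbouring genes of similar sequence whose probes were not checked for cross-hybridisation, were at least 13.4-fold and 6.65-fold higher (adjusted p = 0.038 and 0.015). Dmrta2 (ILMN_1243528), a transcription factor of the developing forebrain, was at least 5.29-fold higher (adjusted p = 0.0119). Ssxb8 (ILMN_2985249), of the cancer-testis SSX family, was at least 4.32-fold higher and Dpep3 (ILMN_2685120), a testis dipeptidase, at least 4.22-fold (adjusted p = 0.015 and 0.0248). Psg23 (ILMN_2972829), a pregnancy-specific glycoprotein, was the only called row detected on control arrays and rose from 10.84 to 14.45, or 12.2-fold (adjusted p = 0.0119). The 2 unnamed rows were ILMN_2846026 and ILMN_2993174, at least 10.5-fold and 4.49-fold higher (adjusted p = 0.0034 and 0.038). None was called lower by limma; at an unadjusted p under 0.05 there were 309 rows higher and 278 lower, a balance that median scaling turned to 241 and 361, and at an adjusted p under 0.10 there were 22 higher and 4 lower. The count rests on how the background was fitted: with background from all rows limma called 0 rows (555 at an unadjusted p under 0.05). It also depends on each mouse. Without control mouse 1 limma called 0 rows (332 at an unadjusted p under 0.05), without control mouse 2 also 0 (199), without transgenic mouse 1 it called 53 and without transgenic mouse 2 it called 850. In the last 2 fits the spread comes from the control mice alone.

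Next to these stood genes that missed the threshold. The 5 that filled the higher group were the beta-defensin Defb4 (at least 3.19-fold), the peptide transporter Slc15a2 (at least 5.07-fold), the centriole gene Sass6 (2.37 on the log2 scale), the lipoprotein receptor Apobr (at least 2.00-fold) and the tubulin Tubb6 (at least 2.61-fold), with adjusted p between 0.0569 and 0.0913. With Dnmt1, the lower group of 12 held Angptl4, an inhibitor of lipoprotein lipase (at least 2.64-fold lower, adjusted p = 0.0913), the scramblase Plscr4 (at least 3.16-fold), the B cell chemokine Cxcl13 (at least 1.85-fold), the homeobox genes Hoxd4 (at least 2.96-fold) and Hoxd8 (at least 1.36-fold), the sialyltransferase St8sia5 (at least 2.21-fold), Agpat5 (at least 1.52-fold) and Klhdc9 (at least 1.41-fold). These 8 were detected on all 4 control arrays and on 0 transgenic arrays. Nccrp1, Abhd1 and the secreted protease inhibitor Wfdc2 had changes of -2.14, -2.66 and -1.53, and the largest adjusted p of the group was 0.150. Both transgenic mice lay above both control mice in 21.7% of rows and below both in 20.9%, where chance gives 16.7% each.

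The transgenic mice differed from each other more than the control mice did. The median SD was 0.118 between single arrays of a mouse (log2). For means of 2 arrays, which vary less than single arrays, it was 0.103 between control mice and 0.215 between transgenic mice. Between single arrays, the SD of log2 differences over rows was 0.171 to 0.245 within a mouse. It was 0.346 to 0.434 between control mice and 0.639 to 0.656 between transgenic mice. Across rows, which are not independent replicates, the control mice correlated at 0.986 and the transgenic mice at 0.954, and transgenic mouse 1 correlated with the control mice at 0.948 and 0.939, against 0.977 and 0.965 for transgenic mouse 2. More rows differed over 2-fold between the transgenic mice (619) than between the control mice (137).

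**Figure D2:**
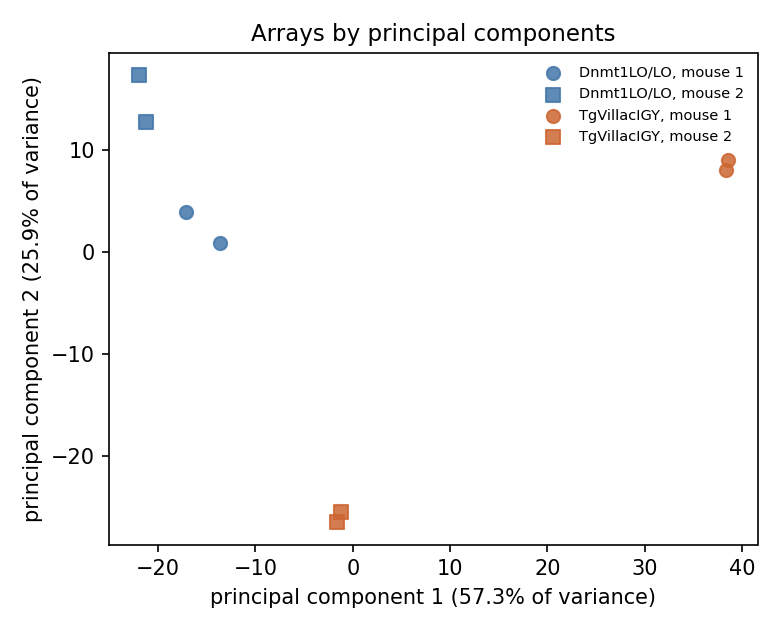
The 8 arrays on the first 2 principal components of the 6982 tested rows (axes give the share of variance). Points of a mouse are its 2 arrays. Component 1 (57.3%) sets transgenic mouse 1 apart from the other 3 mice, and component 2 (25.9%) sets transgenic mouse 2 apart.

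Lists of genes that DNA methylation is known to silence differed in outcome. The list of germline genes with methylated promoters, of which 7 were tested, was called higher (camera adjusted p = 2.0e-11; adjusted p = 0.575 with an estimated correlation, and from 2.5e-20 to 0.575 over its alternatives, whose medians ran from 0.03 to 3.78, with the call kept in 20 of 22), with a median change of 2.99, or 1.40 with members undetected in control mice at their bounds (at 0 for Xlr5a, whose bound is under 1). The median was 0.31 with background from all rows. Of its members, 2 passed over all rows, Rhox5 and Tex19.1, and 6 passed adjusted over the list alone, all higher. Only 7 of the 39 members on the array were detected often enough to be tested, and 5 of these through the transgenic arrays alone, so the detection filter favoured members that differ. Tested without that filter, all 39 had a median of 0.03 and the list was still called (camera adjusted p = 2.0e-05), so the shift lies in part of the list. Of the 39, 0 were detected on all 4 control arrays and no transgenic array. Of 10 imprinted genes, which are expressed from 1 parental copy, 2 passed adjusted over the list alone and 0 over all rows: the cell cycle inhibitor Cdkn1c (1.56 ± 0.25, SE, adjusted p = 0.011 over the list alone) and the growth factor Igf2 (2.16 ± 0.36, SE, adjusted p = 0.011 over the list alone). The imprinted list did not shift (median 0.08, adjusted p = 0.310; -0.02 without control mouse 1). Xlr4a, on both the germline and the strain-variable lists, was higher by 4.84 ± 0.52 (SE, adjusted p = 0.097), and Cd59a, on the strain-variable list, had a change of -1.67 (adjusted p = 0.212). Both passed adjusted over the strain-variable list alone (adjusted p = 0.0041 and 0.0204). The 14 strain-variable genes had a median of -0.22 and a mean of 0.33 and did not shift (adjusted p = 0.905). Their median was -0.51 in transgenic mouse 1 and 0.27 in transgenic mouse 2, and 0.07 without control mouse 1.

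Among epithelial cell types, tuft cell genes rose and absorptive colonocyte genes fell. Tuft cells are rare chemosensory cells, and all 15 tested members of their list had positive changes. Of these, 14 were higher in both transgenic mice than in both control mice. Rows of Alox5, Spib and Fyb, named after their values were seen, passed the detection filter through the transgenic arrays alone. The filter thus favoured members that differ. Without it, the 26 members on the array had a median of 1.12 (camera adjusted p = 1.7e-16). The list rose by a median of 1.46, or 2.76-fold (camera adjusted p = 1.6e-17; adjusted p = 0.575 with an estimated correlation, and from 8.0e-26 to 0.575 over its alternatives, whose medians ran from 0.35 to 1.87, with the call kept in 21 of 23). Adjusted over the list alone, 13 members passed, and over all rows 0. Examples are the G protein subunit Gng13 (1.99 ± 0.23, SE) and Kctd12 (1.43 ± 0.17, SE), with adjusted p = 0.0033 over the list alone and 0.107 and 0.112 over all rows. The medians were 1.87 in transgenic mouse 1 and 1.14 in transgenic mouse 2, and 0.35 over both with background from all rows. Genes of colonocytes, which absorb salt, water and fatty acids, fell by a median of 0.83 over 24 genes (camera adjusted p = 9.1e-06; adjusted p = 0.575 with an estimated correlation, and from 4.1e-11 to 0.575 over its alternatives, whose medians ran from -1.30 to -0.06, with the call kept in 20 of 23), with 23 negative. The median was -1.30 in transgenic mouse 1 and -0.06 in transgenic mouse 2, and without transgenic mouse 1 the list was not called. The sodium channel subunit Scnn1b (-2.06 ± 0.45, SE) and the acute phase protein Saa1 (-1.59 ± 0.39, SE) did not pass (adjusted p = 0.303 and 0.391).

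Stem cell and Wnt target genes rose by a median of 0.47 over 9 genes (camera adjusted p = 0.0057; adjusted p = 0.575 with an estimated correlation, and from 0.000635 to 0.575 over its alternatives, whose medians ran from 0.21 to 0.91, with the call kept in 20 of 23). They were not called without transgenic mouse 1 (median 0.27, against 0.91 in that mouse). The adhesion receptor Cd44 and the Wnt feedback gene Axin2 had changes of 0.74 and 0.82 and did not pass (adjusted p = 0.450 and 0.460). Genes of goblet cells, which make mucus, had a median of 0.11 over 22 genes (adjusted p = 0.662), at 0.25 in transgenic mouse 1 and -0.09 in transgenic mouse 2. They were called higher without mouse 2. The trefoil peptide Tff3 was at -0.77. The glycosyltransferase Galnt12 was at 0.47 (0.74 and 0.20 in transgenic mice 1 and 2, and 0.29 without control mouse 2). Enteroendocrine genes had a median of 0.08 over 17 genes (adjusted p = 0.311), at 0.44 in transgenic mouse 1 and -0.39 in transgenic mouse 2. The median was -0.06 without control mouse 1, and they were called higher without control mouse 2 (0.37) or transgenic mouse 2. The hormones Cck (at least 1.90-fold higher) and Sct (0.91) did not pass (adjusted p = 0.229 and 0.318). Paneth and antimicrobial genes had a median of -0.37 over 13 genes (adjusted p = 0.311), at -1.13 in transgenic mouse 1 and -0.09 in transgenic mouse 2, and at -1.07 without control mouse 1 and -0.02 without control mouse 2. The lectin Reg3a was at least 1.64-fold lower and did not pass (adjusted p = 0.309). The Notch list of 7 genes did not shift (median 0.09, adjusted p = 0.739; 0.19 in transgenic mouse 1 and -0.06 in mouse 2), with the target Hes1 at -0.47 and Nrarp at 0.22.

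**Figure D3:**
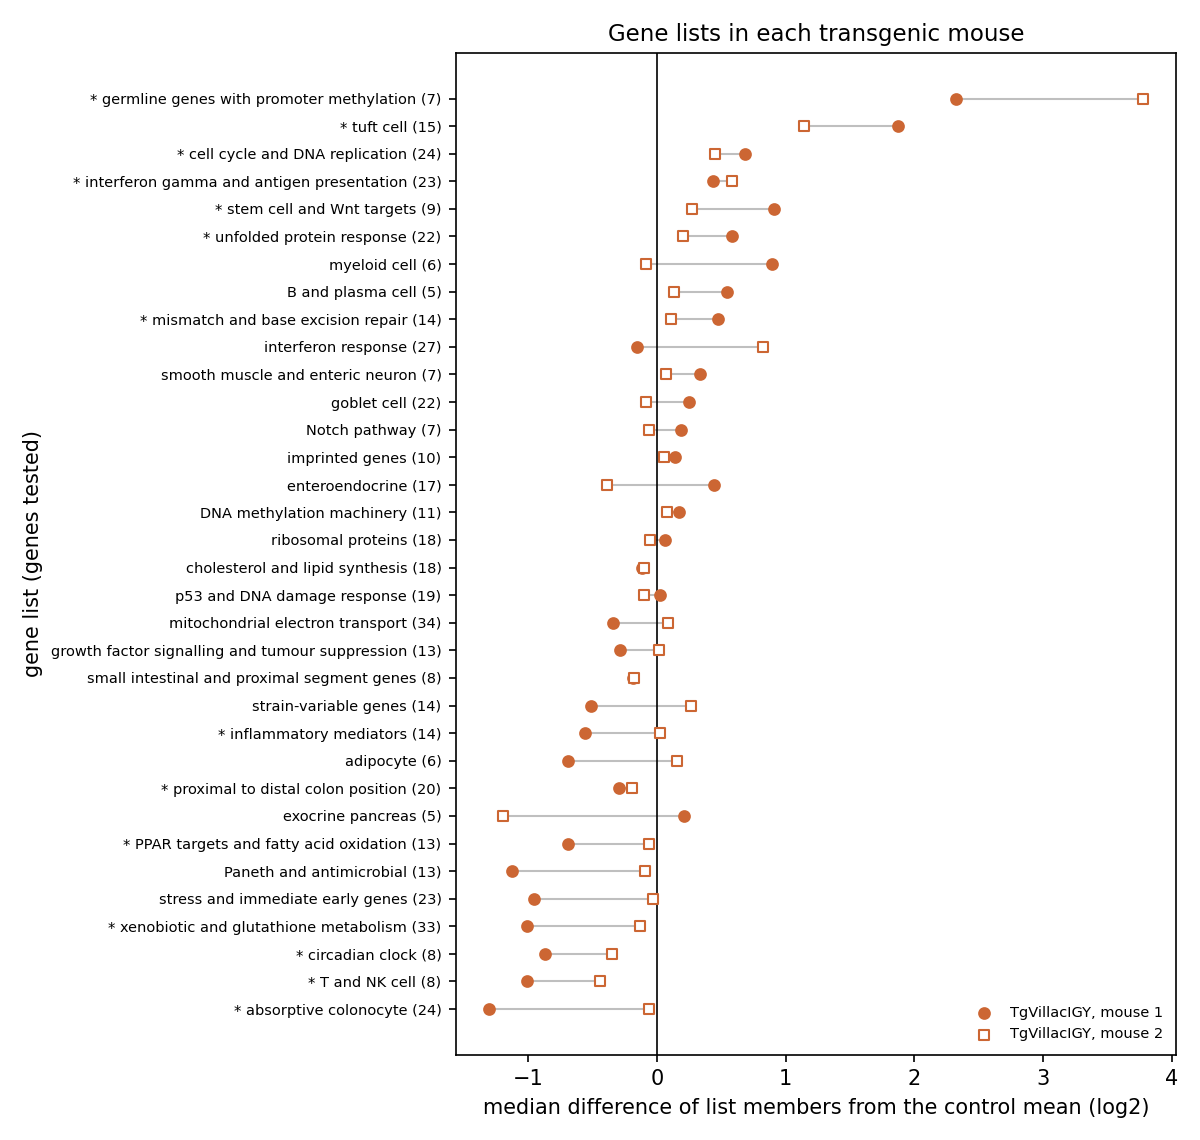
Median difference from the control mean over the tested members of each list (log2, horizontal axis), in transgenic mouse 1 (filled circles) and transgenic mouse 2 (open squares). The vertical axis gives the 34 lists with the number of genes tested, and an asterisk marks the 14 called by camera with a preset correlation. Germline and tuft cell lists lie far above 0 in both mice, whereas colonocyte genes lie at -1.30 and -0.06.

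Immune lists moved in both directions. Antigen presentation and interferon gamma genes rose by a median of 0.53 over 23 genes (camera adjusted p = 4.4e-05; adjusted p = 0.575 with an estimated correlation, and from 1.4e-12 to 0.575 over its alternatives, whose medians ran from -0.03 to 1.06, with the call kept in 21 of 23), with 21 positive. The medians were 0.44 and 0.58 in transgenic mice 1 and 2. The control mice differed in these genes: the median was 1.06 without control mouse 1 and -0.03 without control mouse 2. The MHC class II chaperone Cd74 passed adjusted over the list alone (2.00 ± 0.25, SE, adjusted p = 0.0132), and the class II chain H2-Eb1 did not pass (2.12 ± 0.49, SE). T and NK cell genes fell by a median of 0.70 over 8 genes (camera adjusted p = 0.0171; adjusted p = 0.575 with an estimated correlation, and from 0.00357 to 0.575 over its alternatives, whose medians ran from -1.01 to -0.05, with the call kept in 16 of 22). Of these, 6 were negative and 2 positive, with a mean of -0.37. The receptor chain Cd3d was at -0.99 and the chemokine Ccl5 at -0.76, whereas Prf1 (1.18) and Itgae (0.61), named after their values were seen, were higher in both transgenic mice. The call was also lost with median scaling, with array 2 alone and with background from all rows. The medians were -1.01 and -0.44 in transgenic mice 1 and 2, and without mouse 1 the list was not called. Inflammatory mediators fell by a median of 0.23 over 14 genes (camera adjusted p = 0.0257; adjusted p = 0.575 with an estimated correlation, and from 0.00784 to 0.575 over its alternatives, whose medians ran from -0.56 to 0.02, with the call kept in 15 of 23). Their medians were -0.56 in transgenic mouse 1 and 0.02 in transgenic mouse 2, and without mouse 1 the list was not called. Without control mouse 2 the median was -0.08. The call was also lost with median scaling, with no detection filter, with detection on all 8 arrays, with array 2 alone and with background from all rows. Cxcl13 passed over that list alone (limma, adjusted p = 0.0051), and the cytokine Il18 had a change of -1.33 (-1.92 and -0.73 in transgenic mice 1 and 2).

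Of the remaining cell type lists, none of those tested was called by camera, and the endothelial and fibroblast lists had too few genes to test. Myeloid genes had a median of 0.35 over 6 genes (adjusted p = 0.274), at 0.90 in transgenic mouse 1 and -0.08 in transgenic mouse 2. The macrophage mannose receptor Mrc1 (at least 1.74-fold higher) passed over the list alone (adjusted p = 0.0033), unlike the protease Ctss (-0.60; -1.07 and -0.13 in transgenic mice 1 and 2). B and plasma cell genes had a median of 0.34 over 5 genes (camera adjusted p = 0.310), at 0.55 in transgenic mouse 1 and 0.13 in transgenic mouse 2. Ly6d was at least 1.12-fold higher and Fkbp11 was at 0.90 (1.54 and 0.26 in these mice). Smooth muscle and neuron genes had a median of 0.19 over 7 genes (adjusted p = 0.216), at 0.33 in transgenic mouse 1 and 0.07 in transgenic mouse 2. The creatine kinase Ckb (1.52) passed over the list alone (adjusted p = 0.0404), and smoothelin, Smtn, was at 0.90. Adipocyte genes had a median of -0.24 over 6 genes (adjusted p = 0.704), at -0.69 in transgenic mouse 1 and 0.16 in transgenic mouse 2. Lpl was at -1.13 (-1.89 and -0.36 in these mice) and Dgat2 at -0.69 (-1.22 and -0.17). Exocrine pancreas genes had a median of -0.28 over 5 genes (adjusted p = 0.216; Cela1 -1.20, Zg16 -0.28), at 0.21 in transgenic mouse 1 and -1.20 in transgenic mouse 2. The pancreas list was called lower without control mouse 1 (-0.43) or transgenic mouse 1. Of the endothelial list 4 genes were detected often enough. The clotting factor Vwf (2.96 ± 0.33, SE) and Plvap (at least 1.19-fold higher) passed over the list alone (limma, adjusted p = 0.0013 and 0.0056). Mrc1 and Plvap met the detection filter through the transgenic arrays alone, so the filter favoured them. Of the fibroblast list 1 gene was detected often enough, Timp2 (-0.27, with 0.60 and -1.13 in transgenic mice 1 and 2). The interferon response list of 27 genes did not shift (median 0.30, adjusted p = 0.192); its medians were -0.16 in transgenic mouse 1 and 0.83 in transgenic mouse 2, and Oas2 (1.29; above 2 without control mouse 1 and 0.07 without control mouse 2) and Irf9 (0.42; 0.73 and 0.11) did not pass. Its control mice differed from their mean by medians of 0.71 and -0.71, and leaving out a mouse decided its direction: the median was 0.99 without control mouse 1 and 0.83 without transgenic mouse 1, both called higher, and -0.38 without control mouse 2, called lower.

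Proliferation and protein folding genes rose by small amounts. Cell cycle and replication genes rose by a median of 0.58 over 24 genes (camera adjusted p = 6.8e-11; adjusted p = 0.575 with an estimated correlation, and from 8.3e-14 to 0.575 over its alternatives, whose medians ran from 0.31 to 0.80, with the call kept in 21 of 23). Of these, 23 were positive, 21 were higher in both transgenic mice than in both control mice and 0 passed over the list alone by limma. The medians were 0.68 and 0.45 in transgenic mice 1 and 2. The helicase subunit Mcm7 was at least 1.31-fold higher and the ribonucleotide reductase subunit Rrm2 had a change of 0.81 ± 0.19 (SE). Unfolded protein response genes rose by a median of 0.36 over 22 genes (camera adjusted p = 0.000257; adjusted p = 0.575 with an estimated correlation, and from 9.8e-06 to 0.575 over its alternatives, whose medians ran from 0.15 to 0.58, with the call kept in 21 of 23). The medians were 0.58 and 0.20 in transgenic mice 1 and 2, with the oxidoreductase Ero1b at 0.96 and the chaperone Hspa5 at 0.74. Mismatch and base excision repair genes rose by a median of 0.31 over 14 genes (camera adjusted p = 0.0127; adjusted p = 0.597 with an estimated correlation, and from 0.00434 to 0.597 over its alternatives, whose medians ran from 0.10 to 0.47, with the call kept in 18 of 23). The ligase Lig1 was at 0.64 and the flap endonuclease Fen1 at 0.85. The list was not called without transgenic mouse 1, with medians of 0.47 in that mouse and 0.11 in mouse 2. Nor was it called with no detection filter (median 0.20 over 23 genes, camera adjusted p = 0.181). The p53 and DNA damage list had a median of -0.08 over 19 genes (camera adjusted p = 0.216), and of 0.02 without transgenic mouse 2. Gadd45b (-1.01 ± 0.16, SE) was past the threshold over the list alone (limma, adjusted p = 0.0366). Gadd45a was at -0.91 (-1.32 and -0.51 in transgenic mice 1 and 2). Stress and immediate early genes had a median of -0.51 over 23 genes (adjusted p = 0.0991), at -0.95 in transgenic mouse 1 and -0.03 in transgenic mouse 2. They were called lower without control mouse 2 (-0.48) or transgenic mouse 2. The chaperone Hsph1 (1.17) and Gadd45b passed over that list alone (adjusted p = 0.0221 for both).

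Metabolic genes were lower mainly in transgenic mouse 1. Xenobiotic and glutathione genes fell by a median of 0.62, or 1.53-fold, over 33 genes with 30 negative (camera adjusted p = 3.0e-06; adjusted p = 0.575 with an estimated correlation, and from 1.3e-09 to 0.575 over its alternatives, whose medians ran from -1.01 to -0.13, with the call kept in 20 of 23). Their median was -1.01 in transgenic mouse 1 and -0.13 in transgenic mouse 2, and without mouse 1 the list was not called. The glutathione transferase Gsta4 (-0.85) and the sulfotransferase Sult1c2 (-1.36) did not pass. PPAR target and fatty acid oxidation genes fell by a median of 0.33 over 13 genes, all negative (camera adjusted p = 0.000257; adjusted p = 0.575 with an estimated correlation, and from 1.5e-06 to 0.575 over its alternatives, whose medians ran from -0.69 to -0.06, with the call kept in 20 of 23). Their medians were -0.69 and -0.06 in transgenic mice 1 and 2, and without mouse 1 they were not called. Angptl4 and the P450 enzyme Cyp4b1 (-2.45 ± 0.42, SE) passed over that list alone (adjusted p = 0.0029 and 0.0157). Circadian clock genes fell by a median of 0.64 over 8 genes (camera adjusted p = 0.0028; adjusted p = 0.575 with an estimated correlation, and from 0.000239 to 0.575 over its alternatives, whose medians ran from -0.87 to -0.13, with the call kept in 20 of 23). The repressor Nr1d1 (-1.18 ± 0.21, SE) passed over the list alone (limma, adjusted p = 0.0216). Dbp was at -2.18 (-2.96 without control mouse 1 and -1.39 without control mouse 2). The list's medians were -0.87 and -0.35 in transgenic mice 1 and 2, and it was not called without mouse 1.

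Of the other lists 1 was called. Genes of position along the colon fell by a median of 0.28 over 20 genes (camera adjusted p = 0.0371; adjusted p = 0.575 with an estimated correlation, and from 0.0102 to 0.575 over its alternatives, whose medians ran from -0.34 to -0.07, with the call kept in 17 of 23). They were not called without transgenic mouse 1, with medians of -0.29 in that mouse and -0.20 in mouse 2, nor with no detection filter, array 2 alone or background from all rows. Wfdc2 passed over the list alone (adjusted p = 0.0158), and the transcription factor Osr2 (-1.57; -2.44 and -0.71 in transgenic mice 1 and 2) did not. Cholesterol and lipid synthesis genes had a median of -0.05 over 18 genes (adjusted p = 0.192), at 0.06 without control mouse 1 and called lower without control mouse 2 (-0.13). The sterol oxidase Msmo1 (-1.19) passed over the list alone (adjusted p = 0.0222), and Scd2 was at -0.86. Small intestinal genes had a median of -0.21 over 8 genes (adjusted p = 0.216; Rbp2 -0.85, Gata6 -0.28), at -0.10 without control mouse 2. Growth factor and tumour suppressor genes had a median of -0.21 over 13 genes (adjusted p = 0.310; Egf -0.99, Id3 -0.53), called lower without transgenic mouse 2 (-0.28), at 0.01 without transgenic mouse 1 and at -0.07 without control mouse 2. Mitochondrial electron transport genes had a median of -0.12 over 34 genes (adjusted p = 0.0949; Sdhb -0.37, Cox5a -0.32), at -0.34 in transgenic mouse 1 and 0.09 in transgenic mouse 2, and were called lower without mouse 2. Ribosomal protein genes had a median of -0.01 over 18 genes (mean 0.04, adjusted p = 0.704; Rpl22 0.42, Rps2 0.16), from -0.05 without transgenic mouse 1 to 0.06 without transgenic mouse 2. In all, camera with a preset correlation called 14 of 34 lists, 7 higher and 7 lower, and with an estimated correlation 0, at a smallest adjusted p of 0.575 and with 0 at an unadjusted p under 0.05. Fry called 0 lists in 1 direction (3 at an unadjusted p under 0.05) and 8 for change in either direction. Of the lists camera called, these 8 held germline genes and inflammatory mediators (fry adjusted p = 0.0222 for both), and not tuft cell genes (0.0673). The others were DNA methylation, imprinted, strain-variable, myeloid, stress and cholesterol genes (fry adjusted p from 0.0222 to 0.0371), which camera did not call.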

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

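The tests of array brightness, of a chromosome segment, of colonocyte share (also in transgenic mouse 2 alone), of dim arrays and of crypt base were chosen after the results they bear on were seen. In 9 of 178 groups of 4 arrays, 1 array stood apart from the other 3, and chance gives about 1 in 20. Because 4 arrays come from 2 mice, such gaps mix animals and repeat hybridisations.

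Among control arrays, array 1 of mouse 1 stood apart for Dnmt1 (9.63, the others 9.14 to 9.22), Axin2 (9.69, the others 9.35 to 9.40) and Tff3 (14.25, the others 14.47 to 14.50), all log2. Array 2 of control mouse 1 stood apart for Plscr4 (7.81, the others 7.99 to 8.01), and array 2 of control mouse 2 for Agpat5 (7.04, the others 6.83 to 6.86) and Osr2 (12.88, the others 12.58 to 12.60). Among transgenic arrays, array 1 of mouse 1 stood apart for Slc15a2 (8.68, the others 8.80 to 8.82), array 2 of mouse 1 for Nrarp (10.23, the others 10.34 to 10.36) and array 1 of mouse 2 for Angptl4 (6.14, the others 5.89 to 5.91).

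Part of the germline list was higher in both transgenic mice, with 6 of its 7 tested members above both control mice. All 39 members on the array had a median of 0.03 with no detection filter. The tables argue against brightness or normalization of the arrays, which would act on other genes alike. Of the genes undetected on all control arrays, 5 of 36 germline genes (13.9%) were detected on all 4 transgenic arrays. Of 9691 others, 49 (0.506%) were (Fisher's exact test, two-sided, p = 1.4e-06). With the Rhox genes counted as 1 it was 3 of 34 germline genes (Fisher's exact test, two-sided, p = 0.000769). These few include Xlr5a, which lay near the detection limit (6.35 and 6.38 in transgenic mice 1 and 2, log2). The tables also argue against testis tissue in the samples, since 1 of 18 testis-abundant genes was detected on at least 3 transgenic arrays. That gene, Tssk2, was also detected on at least 3 control arrays. A chromosome segment carried with the transgene stays open for the 5 of the 7 members on the X chromosome. The others lie on 2 more chromosomes. A single segment could not hold Tex19.1, on chromosome 11, as well. Nor could it hold the called genes Dmrta2 and Dpep3, on chromosomes 4 and 8. The 3 splits of the 4 mice into pairs are too few for a share under 0.05; the real split called 9 rows and the highest other 1. Lower Dnmt1 activity, the difference the design names, remains a candidate explanation that was not tested apart from anything else that came with the transgene.

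Tuft cell genes were higher in both transgenic mice. A lower share of colonocytes would raise other cell types alike. The tuft median exceeded the goblet and enteroendocrine medians by at least 1.23 (log2) in each transgenic mouse. For mouse 2 the tables argue against it: the lower quartile of tuft members lay above the upper quartiles of goblet and enteroendocrine members, by at least 0.85, and the colonocyte median was -0.06 against a tuft median of 1.14. In mouse 1 tuft members lay above goblet members by 0.52 between quartiles, but overlapped enteroendocrine members by a small margin (-0.015), and the colonocyte median was -1.30, so there a contribution stays open. Leukocytes that share genes with tuft cells may contribute: the leukocyte-wide median was 0.51 in transgenic mouse 1 and 0.04 in mouse 2, below the bound set in advance, but by less than the spread of its 7 tested genes, which moved both ways (Vav1 2.06 and 1.19, Cd52 -0.45 and -0.78, and Laptm5, the brightest of them at a mean level of 9.56, 1.49 and -0.39). The real split gave a tuft median of 1.46 and the highest other split 0.35, and 3 splits are too few for a share under 0.05. More tuft cells, or more expression per tuft cell, with the genotype stays open and was not tested.

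Transgenic mouse 1 was low in colonocyte and xenobiotic genes, and its arrays were the dimmest. Dim arrays would move genes of like level alike, which the tables argue against: the medians of -1.30 and -1.01 lay below all 10000 random lists matched on level, whose middle 95% ran from -0.20 to 0.23 and from -0.17 to 0.20. In transgenic mouse 2 the xenobiotic median of -0.13 also lay below that of matched lists (-0.105 to 0.096). Its colonocyte median of -0.06 lay within it (-0.115 to 0.107). Another segment of the colon stays open: of the Hox genes of groups 11 to 13 and Prac, named in advance, only Hoxa13 was detected often enough, and the list of position along the colon, which holds genes of both ends, was lower in both transgenic mice (-0.29 and -0.20), with 14 members negative and 6 positive. More crypt base in the piece sampled may contribute: stem cell and cell cycle medians were higher in mouse 1 than in mouse 2, by 0.64 and 0.23, which leaves it open. With 1 mouse, a difference between animals cannot be excluded either.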

How the results depend on the processing

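The background fit over all rows and the detection filter based on signals were added after seeing the data. With 9 rows called, the count stayed between 6 and 13, all higher, under no background correction, normexp, median scaling, cyclic loess, series matrix values, detection on at least 2 arrays, a trended variance prior, a 1.5-fold minimum and either array alone. It was 2 with no detection filter, which adjusts over more rows, 1 with detection on all 8 arrays, which leaves out genes absent in control mice, 15 with the filter on signals, whose cause was not tested, 26 at an adjusted p under 0.10 and 0 with background from all rows, whose larger background SD left smaller changes; the cause was not tested further. Treating the 8 arrays as independent gave 640 (341 higher), which overstates n. The mouse as a random block gave 185 (107 higher), and with the array number as a block as well 137 (87 higher). The block fits use a single correlation between arrays of a mouse for all rows (0.696 and 0.705). They still take degrees of freedom from 8 arrays, so they too can overstate the evidence from 4 mice. The same 9 rows were in each of these array fits. Array numbers do not pair the mice (correlations of array differences between mice -0.24 to 0.14). Leaving out 1 mouse gave 0 to 850 calls; the lone mouse is then assumed to vary like the other genotype. The spread and the group means change together in these fits, and the cause was not tested.

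Dnmt1 was lower under every alternative run, from -2.55 to -0.64. With all 4 mice its limma adjusted p ran from 0.000615 to 0.618. Among these fits it passed the threshold only in the 3 fits of 8 arrays, at -2.20, the one with the array number as a block included. Those 3 fits take degrees of freedom from arrays. With the mouse as the replicate the smallest limma adjusted p was 0.0564, with array 1 alone. Over the mice left out in turn the change in Dnmt1 ran from -2.55 to -1.86, with the spread then taken from the genotype that kept 2 mice. With background from all rows it was -0.64 and with series matrix values -1.73.

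The count of 14 lists became 0 with an estimated correlation and 0 with fry in 1 direction, whose spread rests on 2 residual degrees of freedom; leaving out mice gave 7 to 19, with 5 of the 14 kept at 7, and all other alternatives gave 10 to 16, with 11 of the 14 kept under background from all rows. Fits of 8 arrays gave the same 14, since camera takes no account of the block. The tallies of calls kept by each list count these fits too, though they treat arrays as separate samples. Apart from the estimated correlation and fry, the alternatives in these tallies kept the preset correlation. The interferon response list, not called with all 4 mice, was called lower without control mouse 2 (-0.38) and higher without control mouse 1 (0.99) or transgenic mouse 1 (0.83). Of 86 named genes other than Dnmt1, 1 changed sign, Timp2, in 2 of the 1682 values. With a mouse left out, 24 of the 86 turned or moved by over 1.5 times: 16 without transgenic mouse 1, 15 without transgenic mouse 2, 3 without control mouse 1 and 6 without control mouse 2. Signals near background limit the folds of genes absent in a genotype, given as bounds.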

Other observations

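The tests of gene families, of genes detected in 1 genotype and of X-linked genes were chosen after the values they bear on were seen, in full or in part. Cytochrome P450 genes, which oxidise drugs, steroids and fatty acids, were lower as a family. Among 90 families of tested genes grouped by the start of their symbols, the 20 Cyp genes had a median change of -1.12, with 18 negative (camera adjusted p = 2.7e-06; adjusted p = 0.986 with an estimated correlation), and 7 of them are on the fixed lists. Their median was -1.59 in transgenic mouse 1 and -0.53 in transgenic mouse 2. Some members were low in both mice, such as Cyp2d12 (-2.39 and -1.85) and Cyp2f2 (-2.59 and -1.62), and others in mouse 1, such as Cyp2c65 (-3.42 and 0.35). Nucleoporin genes, which build the nuclear pore, were higher: the 12 Nup genes had a median of 0.31 with 11 positive (camera adjusted p = 0.0117; adjusted p = 0.986 with an estimated correlation), and 0 of them are on a fixed list. Nup210 had the largest change, 0.97, and 0 members of either family passed over all rows (limma). Under the other background and normalization choices the Cyp median ran from -1.13 to -0.59 and the Nup median from 0.12 to 0.30.

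Genes undetected in control mice may become detectable with the transgene. On all 4 transgenic arrays and no control array 68 rows were detected, against 25 rows the other way round, and the other splits of the 4 mice into pairs gave at most 14 in a direction. Detection itself leaned that way, with 6922 to 7053 rows detected on a transgenic array and 6646 to 6918 on a control array, at detection limits of 6.25 to 6.33 and 6.30 to 6.57 (log2). With a common limit of 6.57 on every array the counts were 55 and 37, and at most 13 in the other splits. With a common limit of 6.25 they were 66 and 35, and with levels above 6.57 in 1 genotype and below 6.25 in the other 37 and 14, so the size of the imbalance depends on the limit and this stays open. Of the 68 rows, 3 were not higher after normalization (Otud7b, Klk1b27 and Dnajc19), so detection in 1 genotype alone does not show a gene switching on, and 8 were called and 5 are on the germline list. Names among them, chosen after their values were seen, include the cancer-testis gene Magea2 (at least 3.81-fold higher), Csprs (at least 3.25-fold) and the transcription factor Foxc1 (at least 1.09-fold), none of them past the threshold. Genes detected in control mice alone include the homeobox pair Hoxd4 and Hoxd8 and the keratin Krt14 (at least 3.04-fold lower), which did not pass it either.

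Genes detected in transgenic mice alone might also be X-linked more often. On the X chromosome lay 6 of the 54 placed by the RefSeq table (11.1%), against 4.29% of the 9718 likewise placed genes undetected in control mice (Fisher's exact test, two-sided, p = 0.0273). With the Rhox genes, which form a single cluster, counted as 1, it was 4 of 52 (7.69%, Fisher's exact test, two-sided, p = 0.281), so this stays open. Related neighbours among the 54, Tex19.2 with Tex19.1 and Rhox6 with Rhox5 and Rhox9, are not independent, and their probes were not checked for cross-hybridisation.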
